A study of Arabidopsis thaliana with 18 samples.

How the data were processed

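The series holds 18 Affymetrix ATH1 arrays of RNA from GFP-positive protoplasts of Arabidopsis roots, isolated by fluorescence-activated sorting and amplified in a double cycle before labelling, per the labels' protocols. The deposited values are log2 signals of 22810 probe sets per array, made with GCRMA per the submitters' processing notes, whose version and whose choice of arrays normalized together are not given in the sources used here. Scale and range were checked on the values: every array has the same lowest value of 2.17, and between 28.1% and 31.5% of its probe sets lie within 0.1 of it. GCRMA places dim probe sets close to that floor, so a fold change against such a group depends on the background model. For this reason, where every array of the dimmer group lay below log2 5, the text gives brighter over dimmer as at least N-fold, computed from the brighter group's mean against log2 5, and gives no fold where that is under 1. For the averaged BAP effect the bound is the mean over the zones of the brighter side's mean minus the dimmer side's, with dimmer arrays raised to log2 5, and no size is given where the brighter side lay below log2 5 on every array of a zone. Where only some arrays of the dimmer group reached log2 5, the fitted value is given with their number, and it too depends on the background model. Arrays give no read depth, and the number of arrays limits the precision.

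Arrays were grouped by the root zone, treatment and reporter that the labels give, into 7 groups of 2 or 3 arrays. The labels call the arrays of a group biological replicates. One untreated procambium title carries a 3 in its first part and a replicate number of 2 in its second, and 2 was used. No batch or date is given, so treatment and any batch of plants cannot be told apart.

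All statistics were computed with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with no further scaling. The 64 control probe sets were left out, and probe sets were kept where at least 2 arrays reached log2 5, which left 13202 probe sets over the 16 ARR15::GFP arrays and 13465 over all 18. The 16 arrays were fitted with a mean per group, which left 10 residual degrees of freedom, and comparisons were taken as contrasts with a moderated variance that follows an intensity trend. The comparison with ARR5::GFP cells used all 18 arrays (11 residual degrees of freedom). Calls were made at a Benjamini-Hochberg adjusted p of 0.05 over the probe sets kept. The comparisons were each pair of zones without and with BAP, the BAP effect in each zone, its mean over the 3 zones, and limma's F test of whether it differs between the zones. Errors of log2 levels are SDs over arrays, and standard errors are those of limma. Group tests used camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, on 1 probe set per gene, for lists with at least 5 genes kept. fry asks whether the genes of a list move on balance one way and does not compare them with other genes.

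Of the 22746 probe sets other than controls, 13513 have 1 gene in the platform annotation used here, 503 have several and 8730 are not listed there, and 13436 of the first were matched to the reference gene table. No gene was named from a probe set with several genes, and for a gene with several probe sets the one with the highest mean stands for it. Of the probe sets kept over 16 arrays, 7053 have 1 gene, and 1027 have a symbol other than a locus code. The names RCPG and PEP come from the lists fixed by hand, since the reference table has only their locus codes, and ARR16, IRX10 and GH3.5 of those lists are RR16, GUT2 and WES1 in the reference table.

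Genes were named by a rule set before the data were examined, as were the groups, the tests, the main alternatives and 24 gene lists. The rule takes the 10 largest increases and 10 largest decreases for cambium against procambium without BAP and for the averaged BAP effect, 5 and 5 for every other comparison, and the 10 smallest p-values of the F test with a difference of at least 1 between 2 zones. Named genes passed the adjusted p, changed by at least 1 on the log2 scale, have a symbol, and have groups whose arrays do not overlap. The reporter genes and any member of the fixed lists may be named too. Only 41 of the 372 genes of the fixed lists have a probe set in the annotation and 34 were kept, so that 2 lists, the cambium and procambium regulators and the auxin response genes, could be tested as sets. Another 22 lists of 380 genes were therefore built from the annotated names, after these were seen and before any test, and 20 of them could be tested over the 16 arrays. Genes given as examples of the lists were chosen after their values were seen, those of the added lists among members whose call held without any 1 array, so that examples whose call was lost are not shown. The values of list tests and of F tests with 1 array left out were added after the list results were seen.

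The fits were tested on simulated data made from the kept probe sets' means and spreads, with 200 of 13202 probe sets changed. Of 100 probe sets changed by 1 on the log2 scale, 5 were recovered for cambium against procambium without BAP, and of 100 changed by 2, 57 were, with 4 false calls. For the averaged BAP effect 55 and 94 of 100 were recovered, with 6 false calls, and for the F test 0 and 12, with 0 false calls. The F test simulation changed BAP-treated procambium alone. Noise was drawn independently, and fewer probe sets were changed than the real fits of these comparisons called. The recovered shares and false calls need not hold for the real data. Alternatives were no filter, a filter at log2 7, quantile normalization, centring each array on its median, no intensity trend, array weights, a fit of the compared groups alone, the replicate number as a block, a minimum size of 1 on the log2 scale, leaving out probe sets whose suffix (_s_at or _x_at) marks possible cross-hybridization, and leaving out each array in turn. Where that left 1 array in a group, limma's pooled spread was used, which assumes that the lone array varies like the other groups. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.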

Results

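Gene expression was measured on 18 Affymetrix ATH1 arrays of RNA from GFP-positive protoplasts sorted from Arabidopsis roots. In 16 arrays the sorted cells carried an ARR15::GFP reporter, driven by the promoter of a type-A response regulator that is switched on by cytokinin. The roots of these 8-day seedlings were divided along their length into a basal zone (cambium), a middle zone (transition cambium) and an apical zone (procambium). Untreated plants gave 3 cambium arrays, 2 transition cambium arrays and 2 procambium arrays. Plants moved after 6 days to medium with 100 nM of the synthetic cytokinin BAP for 48 h gave 3 arrays of each zone. The 2 remaining arrays came from ARR5::GFP cells of 6-day seedlings, sorted from undissected lower roots, where the labels place the reporter in procambium and lateral root cap. Between 47.2% and 49.9% of the probe sets reached log2 5 on each array, and 28.1% to 31.5% lay within 0.1 of the lowest value. The number of arrays per group limits the precision. Replicates correlated at r = 0.92 to 0.975 across probe sets, which are not independent replicates. The mean correlation between groups was 0.922 for untreated cambium and transition cambium, and 0.766 for untreated cambium and procambium.

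**Figure D1:**
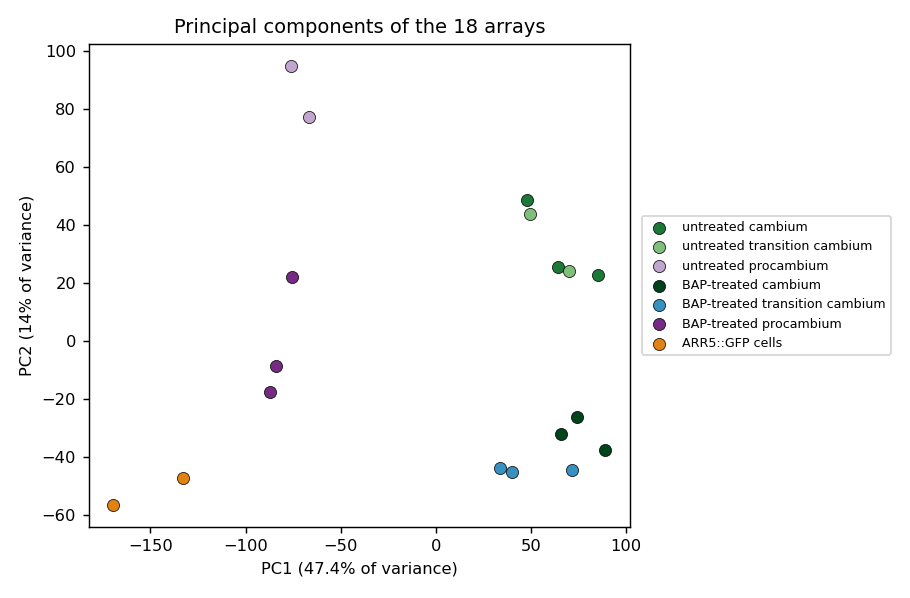
Principal components of the 18 arrays over the probe sets kept, with 1 point per array coloured by group, the first component (47.4% of the variance) on the x axis and the second (14%) on the y axis. Cambium and transition cambium arrays lie on the right, procambium and ARR5::GFP arrays on the left, and BAP-treated arrays lie below the untreated arrays of the same zone.

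The endogenous ARR15 transcript was dim in all untreated sorts, at log2 2.66 ± 0.26 (SD, n = 3) in cambium, 3.02 ± 0.14 (n = 2) in transition cambium and 2.72 ± 0.05 (n = 2) in procambium. After BAP it reached 6.59 ± 0.23, 5.93 ± 0.59 and 6.89 ± 0.72 in the same zones (n = 3 each). Every untreated array lay below the level of log2 5 used here for a probe set to be kept, so no fold between untreated cambium and procambium is given (adjusted p = 0.933 in limma). In ARR5::GFP cells ARR15 stood at 2.88 ± 0.53 (n = 2), also below that level. The array annotation used here pairs no probe set with ARR5 alone, so ARR5 itself has no value.

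The first question was how expression differs along the root, from the apical procambium to the basal cambium, in untreated plants. Each zone was sorted by the same cytokinin-driven reporter, so the cells that passed the sort may also differ between zones. In every zone comparison, such a difference and one within the same kind of cells cannot be told apart. PDF2.1, which encodes a plant defensin, was at least 106-fold higher in cambium than in procambium, with log2 levels of 11.72 ± 0.55 (n = 3) against 2.36 ± 0.04 (n = 2). BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis, was at least 51-fold higher, and GH9B8, a member of the family 9 glycosyl hydrolases of the cell wall, at least 43.6-fold higher. The wall-loosening beta-expansin EXPB3 was 113-fold higher (log2 6.81, standard error 0.58). In the other direction, the xyloglucan-modifying enzyme gene XTH16 was lower by -5.44 on the log2 scale (standard error 0.81), and the alpha-expansin EXPA9 was at least 11-fold lower in cambium than in procambium. Of 13202 probe sets tested, 4720 were called, with 2424 higher and 2296 lower in cambium, against 2292 and 2427 with each array centred on its median and 2328 and 2340 with quantile normalization. EXPB3 reached log2 5 on 1 of 2 procambium arrays, and XTH16 on 1 of 3 cambium arrays. Both procambium arrays lay on one side of all 3 cambium arrays for each of these genes, as the naming rule requires.

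Among the 10 genes with the largest increase were also JAL22, a jacalin-related lectin (log2 6.76), HPR, the photorespiratory hydroxypyruvate reductase (at least 12.8-fold), PSAE-1, a photosystem I subunit (at least 32.9-fold), the terpene synthase gene TPS-CIN (at least 12.6-fold), the flavonol glycosyltransferase gene UGT78D1 (at least 15.8-fold) and ALDH11A3 (at least 8.2-fold). The 10 largest decreases held the serine carboxypeptidase-like genes scpl40 (at least 10.5-fold lower) and SCPL34 (at least 14.6-fold lower), CP1 (log2 -5.04), TBL41 (-4.65), sks15 (at least 3.56-fold lower), the glucosyltransferase gene UGT76B1 (-4.38), XTH21 (at least 7.02-fold lower) and the beta-tubulin gene TUB1 (-4.10). Their adjusted p-values ran up to 0.00232, that of UGT76B1, and the 20 calls held without any 1 of the 5 arrays. JAL22 reached log2 5 on 1 of 2 procambium arrays, TBL41 on 1 of 3 cambium arrays and UGT76B1 on 2 of 3.

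Of the 5 regulators of cambium and procambium that were kept, from 6 with a probe set, 4 were higher in cambium, and 5 when adjusted over the list alone. CLE41 and CLE44 encode the TDIF peptide, which promotes the division of vascular stem cells and holds back xylem differentiation. CLE41 stood at 8.72 ± 0.24 in cambium (n = 3) and 5.16 ± 0.62 in procambium (n = 2), an 11.9-fold difference (standard error 0.36 on the log2 scale, adjusted p = 6.01e-06, 1 of 2 procambium arrays at log2 5 or more), and CLE44 was at least 3.1-fold higher. MOL1, a receptor-like kinase that restrains cambium activity, was 6.56-fold higher (log2 2.71, standard error 0.30). LHW, a bHLH factor needed for vascular cell divisions, was 1.75-fold higher (adjusted p = 0.0181), a call lost without untreated cambium replicate 2 (adjusted p = 0.0648) or procambium replicate 1 (0.164). PHV, a class III HD-ZIP factor, differed by 0.85 on the log2 scale (standard error 0.39, adjusted p = 0.105). The 5 kept genes moved up as a set by camera (adjusted p = 0.00026, and adjusted p = 0.00902 with an estimated correlation), and this call held without any 1 array. Most of the fixed list, PXY and ANT included, has no probe set in the annotation used here, so the test covers only these genes. The auxin response list, the other one with enough genes, was not called, with 1 of its 7 kept genes, from 9 with a probe set, higher and 2 lower over all genes as over the list alone (adjusted p = 0.911).

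Photosynthesis genes were higher in cambium. Of 39 plastid-encoded photosynthesis genes 37 were higher, among them psbA of the photosystem II core (log2 4.76, standard error 0.71), and of 16 nuclear genes for photosynthesis and chlorophyll 15 were higher. LHCB4.1, a photosystem II antenna protein, was 23.1-fold higher (10.81 ± 1.09 against 6.28 ± 0.40) and RCA, the Rubisco activase, 32.5-fold higher (1 of 2 procambium arrays at log2 5 or more). The adjusted p-values of camera were 1.05e-15 and 1.57e-09, but both lists gave adjusted p = 0.285 with an estimated correlation. Of 16 genes of the TBL family, which acetylates wall polysaccharides, 3 were higher, such as TBL36 (log2 3.42), and 10 lower, such as TBL21 (-3.86, 1 of 3 cambium arrays at log2 5 or more), with adjusted p = 0.0168, and adjusted p = 0.2 with an estimated correlation. Of 13 wounding, calcium and defence genes 7 were higher and 1 lower, with the receptor-like kinase BIK1 at 2.69 and WRKY6 at -2.78 (adjusted p = 0.0402, and adjusted p = 0.504 with an estimated correlation). That call was lost without untreated cambium replicate 3 (adjusted p = 0.0671) or procambium replicate 2 (0.164). These lists were added after the array's gene names were seen and before any test.

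The comparison of untreated transition cambium with procambium used the same 2 procambium arrays as that of cambium. BCAT4 was at least 14.5-fold higher (8.86 ± 1.33 against 2.44 ± 0.38, n = 2 each), GH9B8 at least 26.9-fold, and BGLU44, a beta-glucosidase, at least 12.6-fold. JAL22 was 76.4-fold and EXPB3 60.6-fold higher (log2 6.25 and 5.92, standard errors 0.65 and 0.64), each at log2 5 or more on 1 of 2 procambium arrays. XTH16 was at least 14.7-fold lower, SCPL34 at least 14.6-fold, TBL41 at least 14.8-fold, EXPA9 at least 11-fold and scpl40 at least 10.5-fold. Of the cambium and procambium regulators, 4 of 5 were higher, and 5 when adjusted over the list alone, with CLE41 7.69-fold (1 of 2 procambium arrays at log2 5 or more), MOL1 5.63-fold and LHW 2.91-fold higher, CLE44 at least 1.12-fold higher (1 of 2 transition cambium arrays), and PHV at 0.98 on the log2 scale (adjusted p = 0.103). The camera test gave adjusted p = 0.000281, and adjusted p = 0.0093 with an estimated correlation. In all, 3720 probe sets were called, 2066 higher and 1654 lower in transition cambium, against 1763 and 1926 with each array centred on its median and 1827 and 1798 with quantile normalization. The count was 1924 without untreated transition cambium replicate 1. The median over all kept probe sets was 0.124 on the log2 scale, and -0.012 with each array centred on its median.

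Of the plastid-encoded photosynthesis genes 23 of 39 were higher in transition cambium than in procambium (adjusted p = 3.4e-08, and adjusted p = 0.522 with an estimated correlation), a call that held without any 1 array. Of the TBL genes 3 were higher and 8 lower of 16 (adjusted p = 0.0343, and adjusted p = 0.237 with an estimated correlation), lost without untreated transition cambium replicate 2 (0.0694) or procambium replicate 1 (0.0754). Of the nuclear photosynthesis genes 4 of 16 were higher (adjusted p = 0.0489, and adjusted p = 0.903 with an estimated correlation), which was lost without any 1 of the 4 arrays: 0.1 and 0.0694 without transition cambium replicates 1 and 2, and 0.0635 and 0.135 without procambium replicates 1 and 2. Of the wounding, calcium and defence genes 7 were higher and 1 lower of 13 (adjusted p = 0.0489, and adjusted p = 0.537 with an estimated correlation), lost without untreated transition cambium replicate 1 (0.142) or procambium replicate 2 (0.152).

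Untreated cambium and transition cambium were closer to each other. PSAE-1 was 34.9-fold higher in cambium (10.04 ± 1.04, n = 3, against 4.92 ± 0.46, n = 2, of which 1 reached log2 5), and PSAN, another photosystem I subunit, 18.3-fold higher. PDF2.1 was 18.9-fold higher, SBPASE, a Calvin cycle enzyme, at least 3.19-fold (2 of 3 cambium arrays at log2 5 or more), and ALDH11A3 at least 8.2-fold. GH9B5 was at least 1.85-fold lower in cambium, and GUT2, a xylan synthesis gene also named IRX10 (2 of 3 cambium arrays at log2 5 or more), scpl48 and the ATP-citrate lyase gene ACLA-2 differed by -3.31, -1.71 and -1.62 on the log2 scale. In limma 100 probe sets were called, 79 higher and 21 lower in cambium, against 16 without untreated transition cambium replicate 1 and 219 without untreated cambium replicate 2. With the arrays of these 2 groups alone in limma none was called, and 856 had an unadjusted p under 0.05.

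Of these 9 genes PSAE-1 alone kept its call without any 1 array. Without untreated transition cambium replicate 1, PDF2.1 (adjusted p = 0.0573), PSAN (0.173), SBPASE (0.301), GH9B5 (0.104), GUT2 (0.627), scpl48 (0.154) and ACLA-2 (0.527) were lost. Without transition cambium replicate 2, PSAN (0.0734), SBPASE (0.151), ALDH11A3 (0.0934) and ACLA-2 (0.0616) were lost. SBPASE, GUT2 and ACLA-2 were also lost without cambium replicate 1 (0.0968, 0.145 and 0.11) or cambium replicate 3 (0.0987, 0.0991 and 0.061). Of the nuclear photosynthesis genes 5 of 16 were higher in cambium (camera adjusted p = 2.92e-21, and adjusted p = 0.162 with an estimated correlation), and of the plastid-encoded ones 0 of 39 were called singly in limma and 13 had an unadjusted p under 0.05 (camera adjusted p = 1.63e-11, and adjusted p = 0.382 with an estimated correlation). Both set calls held without any 1 array, and fry called 0 of the 20 added lists.

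After BAP, cambium and procambium differed in 4099 probe sets, 2155 higher and 1944 lower in cambium. ATMPK13, a mitogen-activated protein kinase gene, was at least 14-fold higher in cambium (8.81 ± 0.71 against 2.31 ± 0.23, n = 3 each), and the beta-glucosidase gene BGLU47 at least 7.95-fold. UGT78D1 was 81.5-fold, PDF2.1 53.3-fold and SP1L2 51.5-fold higher. On the procambium side, hemb2 was at least 77.9-fold, sks15 at least 72.5-fold, SCPL34 at least 53-fold and GH9B6 at least 22.1-fold lower in cambium, and sks16 was at -6.67 on the log2 scale (standard error 0.98). UGT78D1 and SP1L2 reached log2 5 on 1 of 3 procambium arrays each, PDF2.1 on 2 of 3, and sks16 on 1 of 3 cambium arrays. All 10 calls held without any 1 array. RCPG, a root cap polygalacturonase gene, stood at 10.95 ± 0.58 in this procambium sort (n = 3) and 3.35 ± 0.57 in the untreated one (n = 2). RCPG, hemb2, sks16 and GH9B6 were also bright in ARR5::GFP cells, at means of 14.01, 12.34, 12.47 and 10.43.

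Among the cambium and procambium regulators 4 of 5 were higher in BAP-treated cambium than procambium, and 4 when adjusted over the list alone (camera adjusted p = 0.000376, and adjusted p = 0.0104 with an estimated correlation). CLE41 was 3.72-fold, MOL1 4.06-fold and PHV 4.73-fold higher, and CLE44 at least 3.49-fold. LHW differed by 0.25 on the log2 scale (standard error 0.22, adjusted p = 0.434). Beta-glucosidases (7 higher and 1 lower of 12, adjusted p = 0.00199) gave adjusted p = 0.256 with an estimated correlation. Plastid-encoded and nuclear photosynthesis genes (16 of 39 and 11 of 16 higher, adjusted p = 0.00016 and 0.000223) gave adjusted p = 0.523 and 0.462 with an estimated correlation. Genes of mitosis and cytokinesis (6 of 10 higher, adjusted p = 0.0171) gave adjusted p = 0.424 with an estimated correlation. Fold changes of cambium against procambium without and with BAP, which share no array, correlated at r = 0.658 (Spearman 0.618) across probe sets, which are not independent replicates. Both comparisons called 1195 probe sets higher, where independent lists would share 395.7, and 1049 lower, where they would share 338.1.

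BAP-treated transition cambium against procambium gave 3863 calls, 2076 higher and 1787 lower (1919 and 1968 with each array centred on its median), and 2575 without BAP-treated transition cambium replicate 3. ATMPK13 was at least 13.4-fold and PTL, a trihelix transcription factor, at least 5.96-fold higher (7.58 ± 0.24 against 2.19 ± 0.04, n = 3 each), and PDF2.1 was 83-fold, SP1L2 66.5-fold and EXPB3 42.7-fold higher. GH9C1 was at least 6.78-fold and TBL21 at least 5.3-fold lower, and GH9B6, hemb2 and UPB1, a bHLH factor of the root's transition to elongation, were at -4.59, -4.34 and -4.25 on the log2 scale. PDF2.1 reached log2 5 on 2 of 3 procambium arrays and SP1L2 on 1 of 3, and GH9B6 and hemb2 on 2 of 3 transition cambium arrays each. The regulator list was again higher in 4 of 5 genes, and in 4 when adjusted over the list alone (camera adjusted p = 0.000622, and adjusted p = 0.0128 with an estimated correlation). Of the tubulins 6 were higher and 1 lower of 7 (adjusted p = 0.0201, and adjusted p = 0.584 with an estimated correlation).

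BAP-treated cambium against transition cambium gave 167 calls, 79 higher and 88 lower. ALDH3F1 was 14.1-fold higher in cambium (8.16 ± 0.54 against 4.35 ± 1.3, n = 3 each, 1 of 3 transition cambium arrays at log2 5 or more) and GH3.3, which conjugates auxin to amino acids, 8.74-fold. BGLU28 was at least 1.51-fold, the subtilase gene SBT1.3 at least 1.48-fold and ARPN at least 1.15-fold higher. sks15 was at least 8.5-fold, TPS-CIN at least 3.58-fold, hemb2 at least 3.84-fold and SCPL34 at least 3.41-fold lower, and BAT1 was at -2.85 on the log2 scale (1 of 3 cambium arrays at log2 5 or more). In the brighter group, BGLU28, ARPN, hemb2 and SCPL34 reached log2 5 on 2 of 3 arrays each. The count was 86, 105 and 97 without BAP-treated cambium replicates 1, 2 and 3, and 108 and 76 without BAP-treated transition cambium replicates 1 and 2. Without these 5 arrays in the same order, hemb2 was lost at adjusted p = 0.111, 0.098, 0.0834, 0.131 and 0.159, SCPL34 at 0.18, 0.0988, 0.0804, 0.182 and 0.189, and ARPN at 0.19, 0.0972, 0.137, 0.14 and 0.158, and ARPN also without transition cambium replicate 3 (0.0973). With only these 2 groups in the limma fit, ALDH3F1 (adjusted p = 0.0708), BGLU28 (0.102), sks15 (0.1), TPS-CIN (0.0714) and BAT1 (0.0698) lost their calls. In that fit hemb2 (0.179) and SCPL34 (0.192) were lost as well. By camera, 0 of the 2 fixed lists were called (0 at an unadjusted p under 0.05), and 0 of the 20 added lists (5 at an unadjusted p under 0.05), and fry called 0 of either.

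The second question was what BAP changed within each zone and over all of them. The cells were sorted by a reporter that cytokinin switches on, so BAP may also have changed which cells passed the sort. In every BAP comparison, such a shift and a change within the same cells cannot be told apart. Averaged over the zones, ARR15 rose at least 2.77-fold (adjusted p = 1.44e-07) and RR16, the type-A response regulator ARR16, at least 1.75-fold (adjusted p = 5.77e-08), since both lay below log2 5 on all 7 untreated arrays. Type-A regulators are early targets of cytokinin signalling and act back on it, and both of the kept members of the list rose, over all genes and adjusted over the list alone. In cambium, transition cambium and procambium ARR15 was at least 3-fold, 1.9-fold and 3.7-fold higher with BAP, and ARR16 at least 1.02-fold (2 of 3 BAP-treated arrays at log2 5 or more), 1.47-fold and 3.58-fold. Every BAP-treated array lay above every untreated array of its zone for both genes, as the naming rule requires. In all, 3984 probe sets were called (2008 up and 1976 down, and 2004 and 2030 with quantile normalization), of which 1820 changed by at least 1 on the log2 scale. With probe sets higher in ARR5::GFP cells than in untreated transition cambium left out, a choice made after seeing the data, 1326 were up and 1734 down. The untreated transition cambium arrays enter both this choice and the averaged effect, so the choice by itself can shift that split.

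**Figure D2:**
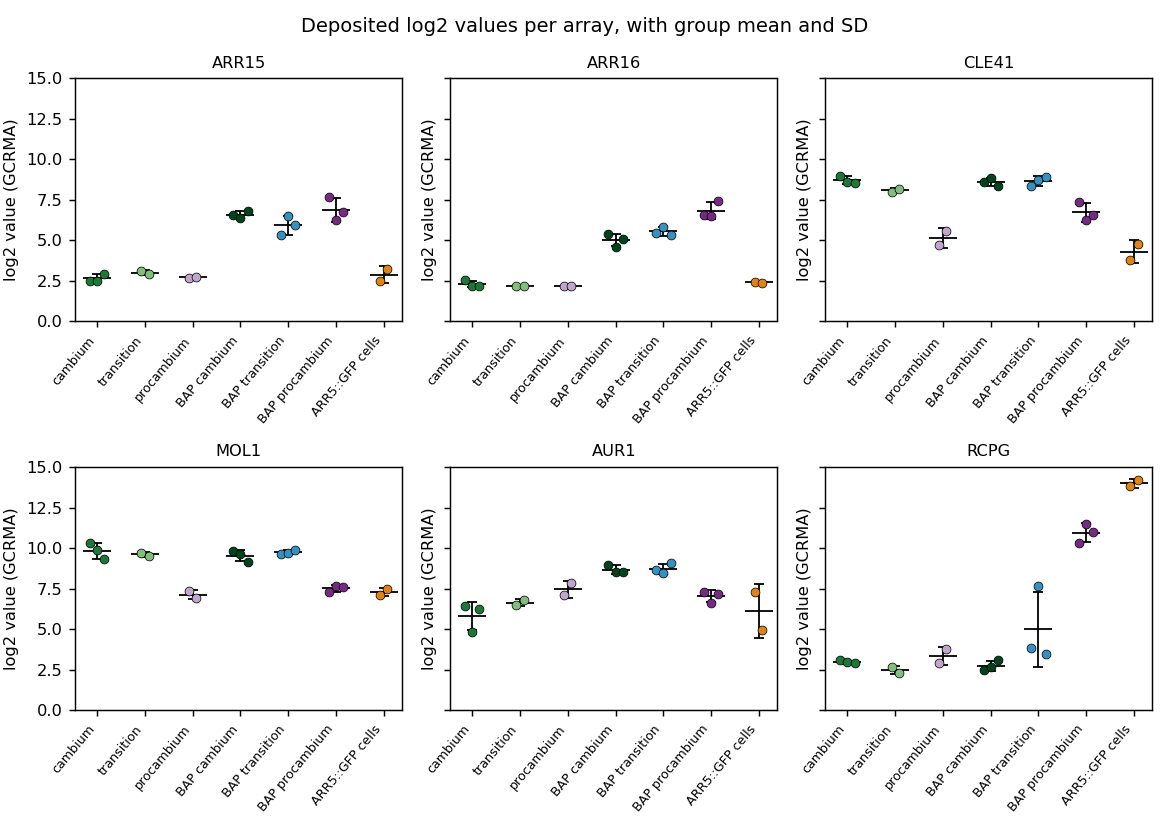
Deposited log2 values of 6 genes on each array, with 1 point per array, grouped by sort on the x axis, and lines for the group mean and SD. ARR15 and ARR16 are higher in all BAP-treated sorts, CLE41 and MOL1 are lowest in procambium and ARR5::GFP cells, and RCPG is high in BAP-treated procambium (10.95) and ARR5::GFP cells (14.01).

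Other genes that rose with BAP over the zones were ATC, a TERMINAL FLOWER relative that delays flowering (log2 3.97, standard error 0.54), the carboxylesterase gene CXE18 (at least 5.38-fold), ATLP-1 (2.26), STR18 (2.24) and JAL22 (2.18). Genes that fell were TBL34 (at least 3.42-fold), the peroxidase gene Prx37 (-2.34), BAT1, which inactivates brassinosteroids (-2.31), the expansin-like gene EXLB1 (at least 2.39-fold), SFP1 (at least 1.89-fold), PSAN (-1.86), the allantoinase gene ALN (at least 2.44-fold), MYBC1 (-1.68) and APS4, an ATP sulfurylase (-1.60). NAMT1, ZCF125 and KINESIN-12B, a motor of the cell division plate, also rose and IAA29, an auxin-responsive repressor, fell, without a size here because each lay below log2 5 with and without BAP in 1 zone. ATC reached log2 5 on 5 of 7 untreated arrays, and STR18 and JAL22 on 6 each, and Prx37 and PSAN did on 6 and BAT1 on 7 of 9 BAP-treated arrays. Each of these calls held without any 1 array.

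Of 10 genes of mitosis and cytokinesis, 8 rose with BAP over the zones, among them the Aurora kinase gene AUR1 (2.84-fold, standard error 0.24 on the log2 scale, 6 of 7 untreated arrays at log2 5 or more), the spindle checkpoint gene BUB3.1 (2.65-fold) and TOPII, a type II topoisomerase (2.70-fold). The camera test gave adjusted p = 0.000543, and adjusted p = 0.365 with an estimated correlation. By zone, AUR1 changed by 2.85 in cambium, 2.07 in transition cambium and -0.40 in procambium on the log2 scale. Camera with the preset correlation called this list for BAP in cambium and in transition cambium, but not in procambium. The list as a set was not tested for a difference between zones. Of 30 UDP-glycosyltransferases 13 rose and 2 fell (adjusted p = 0.0237, and adjusted p = 0.532 with an estimated correlation), such as UGT72E2, which glucosylates monolignols (3.46-fold). Of 12 beta-glucosidases 6 rose and 1 fell (adjusted p = 0.0259, and adjusted p = 0.365 with an estimated correlation). Of 13 wounding, calcium and defence genes 5 rose, with WRKY6 at 3.5-fold, and 1 fell (adjusted p = 0.03, and adjusted p = 0.532 with an estimated correlation). The last 3 calls were lost without untreated procambium replicate 2 (adjusted p = 0.0903, 0.0685 and 0.0903), and the last also without untreated transition cambium replicate 2 (0.0642). In the fixed list of cytokinin degradation and conjugation, UGT76C2, which N-glucosylates cytokinins, rose 1.92-fold (adjusted p = 0.00153) and UGT76C1 did not pass the test (adjusted p = 0.534), so 1 of 2 rose, and 1 adjusted over the list alone.

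Of 7 kept auxin response genes 4 fell with BAP over the zones and 1 rose, in the same numbers when adjusted over the list alone. LBD16, a lateral root regulator, fell at least 2.14-fold, and the auxin-conjugating genes GH3.5 and GH3.3 were at -1.74 and -1.16 on the log2 scale, while GH3.17 rose by 1.56. GH3.5 reached log2 5 on 8 of 9 BAP-treated arrays and GH3.17 on 6 of 7 untreated arrays. As a set the list was not called by camera (adjusted p = 0.0951, and adjusted p = 0.372 with an estimated correlation), so that 0 of 2 fixed lists were called, with 1 at an unadjusted p under 0.05, 1 by fry, and 1 without untreated procambium replicate 2. Both kept genes of the xylem and secondary wall list fell on average over the zones, and both adjusted over the list alone. IRX10, the GUT2 of the zone comparison, was at least 2.53-fold lower on average. IRX10 went from 5.8 to 6.15 in cambium, 9.12 to 6.06 in transition cambium and 6.31 to 4.59 in procambium. The untreated transition cambium mean had an SD of 1.69 (n = 2). IRX15, the other gene, had a mean above log2 5 in untreated transition cambium alone (6.35 ± 1.57, n = 2). Among the cambium and procambium regulators CLE41 rose 1.60-fold (adjusted p = 0.0187, and 0.0682 without untreated procambium replicate 1, with 6 of 7 untreated arrays at log2 5 or more) and LHW fell by 0.58, so that 1 rose and 1 fell of 5, and 1 rose and 2 fell adjusted over the list alone. By zone, CLE41 went from 8.72 to 8.62 in cambium, 8.1 to 8.67 in transition cambium and 5.16 to 6.72 in procambium. LHW changed with BAP by -0.44, -1.44 and 0.12 on the log2 scale in the same zones (F test adjusted p = 0.0285). The root cap gene RCPG, the 1 kept member of its list, rose (adjusted p = 0.000174), with no size given because it lay below log2 5 in cambium with and without BAP.

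In cambium alone BAP changed 1962 probe sets, 1018 up and 944 down. BGLU47 rose at least 7.95-fold (7.99 ± 0.67 against 3.31 ± 0.86, n = 3 each), CYP84A4, a cytochrome P450, at least 6.69-fold, UGT84A4 at least 2.55-fold and BGLU28 at least 1.51-fold (2 of 3 BAP-treated arrays at log2 5 or more). TPS-CIN fell at least 12.6-fold, BAT1 17.5-fold, PSAN 10.7-fold, LBD16 at least 2.64-fold and PIFI at least 2.1-fold (2 of 3 untreated arrays). Of the 10 genes of mitosis and cytokinesis 7 rose, with AUR1 up 7.19-fold and KINESIN-12B up 8.54-fold (camera adjusted p = 9.28e-06, and adjusted p = 0.261 with an estimated correlation). Of the nuclear photosynthesis genes 10 of 16 fell, with LIL3:1, a chlorophyll synthesis gene, down 8.59-fold, and 6 of 39 plastid-encoded ones fell (adjusted p = 1.78e-06 and 2.19e-07, and adjusted p = 0.305 for both with an estimated correlation). Core histones (3 of 5 up, adjusted p = 0.00837) gave adjusted p = 0.305 with an estimated correlation, and chaperone genes (5 of 13 up, adjusted p = 0.00104) gave adjusted p = 0.261. AUR1 reached log2 5 on 2 and KINESIN-12B on 1 of 3 untreated arrays, and BAT1 on 1 and LIL3:1 on 2 of 3 BAP-treated arrays. These named calls held without any 1 array. With only the compared groups in the limma fit, PIFI (adjusted p = 0.0714) and PSAN (0.0507) lost theirs. The count of calls was 1019 without BAP-treated cambium replicate 1 and 1138 without replicate 3.

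In transition cambium BAP changed 1241 probe sets, 621 up and 620 down. SP1L2, of the SPIRAL family of microtubule proteins, rose at least 42.7-fold (10.42 ± 0.40, n = 3, against 3.92 ± 1.29, n = 2), PPDK, pyruvate orthophosphate dikinase, at least 12-fold, sks15 at least 8.5-fold and BGLU47 at least 3.43-fold, and ATC rose 40.3-fold (1 of 2 untreated arrays at log2 5 or more). ARPN fell at least 6.71-fold, TBL34 at least 5.11-fold, the glutaredoxin gene ROXY1 at least 2.49-fold, GH9B5 at least 1.85-fold and BCAT4 was at -4.2 on the log2 scale (1 of 3 BAP-treated arrays). Of the 7 auxin response genes 3 fell, and 4 fell and 1 rose when adjusted over the list alone, with GH3.3 at -2.53, GH3.5 at -2.23 (2 of 3 BAP-treated arrays at log2 5 or more) and LBD16 at least 1.74-fold lower (camera adjusted p = 0.0438, and adjusted p = 0.263 with an estimated correlation). Genes of mitosis and cytokinesis rose in 3 of 10 cases (adjusted p = 0.00853, and adjusted p = 0.415 with an estimated correlation), a call lost without untreated transition cambium replicate 2 (0.173).

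Some of these calls were lost when 1 array was left out. Without untreated transition cambium replicate 1 the count fell to 704 and the adjusted p was 0.0577 for ATC, 0.0578 for GH3.3, 0.0502 for GH3.5, 0.104 for LBD16 and 0.127 for the auxin response list. Without untreated transition cambium replicate 2 the count was 516 and the adjusted p was 0.218 for BCAT4, 0.0588 for GH3.3, 0.134 for GH3.5 and 0.112 for LBD16. Without BAP-treated transition cambium replicate 1 the count was 753. Without replicate 2 of that group BCAT4 (0.0764), GH3.5 (0.0565) and the auxin response list (0.059) were lost, and without replicate 3 BCAT4 (0.0571), LBD16 (0.0752) and the auxin response list (0.081). Where the call was lost, ATC was at 3.89 on the log2 scale against 5.33 with all arrays, BCAT4 between -3.26 and -4.14, GH3.3 at -2.48 and -2.57, and GH3.5 between -1.92 and -2.48.

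In procambium BAP changed 1855 probe sets, 1005 up and 850 down. hemb2 rose at least 77.9-fold (11.28 ± 0.24, n = 3, against 3.77 ± 1.43, n = 2), sks16 at least 44.5-fold, GH9B6 at least 22.1-fold and the carboxypeptidase-like gene scpl28 at least 4.6-fold (2 of 3 BAP-treated arrays at log2 5 or more), and PPDK rose 166-fold (1 of 2 untreated arrays). XTH21 fell at least 7.02-fold, the subtilase gene SBTI1.1 at least 5.67-fold, IAA29 at least 1.66-fold, and TBL34 and XTH16 were at -4.16 and -3.62 on the log2 scale (1 and 2 of 3 BAP-treated arrays). RCPG rose at least 61.7-fold (adjusted p = 3.78e-05). RCPG, hemb2, sks16, GH9B6 and scpl28 were also bright in ARR5::GFP cells, at means of 14.01, 12.34, 12.47, 10.43 and 10.78. For such genes, cells of another type in this sort stay a candidate explanation. Of the 13 wounding, calcium and defence genes 6 rose, among them WRKY53, a senescence and defence regulator (4.83-fold), with adjusted p = 0.00135, and adjusted p = 0.416 with an estimated correlation. EXPA7, a root hair expansin, did not pass the test (adjusted p = 0.143), with 2 of 3 BAP-treated arrays and 0 of 2 untreated arrays at log2 5 or more. CLE41 rose 2.97-fold (1 of 2 untreated arrays) and PHV fell by 1.61, calls lost without untreated procambium replicate 1 (adjusted p = 0.122 and 0.104), when the count of calls was 1185. XTH16 was lost without untreated procambium replicate 2 (0.0927). With probe sets higher in ARR5::GFP cells than in untreated transition cambium left out, a choice made after seeing the data, 1161 were called, 515 up and 646 down.

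The BAP effect differed between the zones for 999 probe sets by limma's F test. The difference between cambium and procambium was called for 1184 probe sets, between transition cambium and procambium for 696, and between cambium and transition cambium for 49. NANA, an aspartic protease of the chloroplast, rose with BAP by 2.60 in cambium and 2.95 in transition cambium and fell by 3.47 in procambium (standard errors 0.45, 0.51 and 0.51, F test adjusted p = 0.000125), where 1 of 3 BAP-treated arrays reached log2 5. In procambium GH9B6 rose at least 22.1-fold and RCPG at least 61.7-fold, and both lay below log2 5 on every cambium array (F test adjusted p = 0.00049 and 0.00259). The rise of GH9B6 was also called in transition cambium (limma adjusted p = 0.035), with 2 of 3 BAP-treated arrays at log2 5 or more. There RCPG stood at 3.83, 7.65 and 3.49 on BAP-treated replicates 1, 2 and 3. BGLU47 rose at least 7.95-fold in cambium and lay below log2 5 on every procambium array (adjusted p = 0.00159). AUR1 was at 2.85 in cambium, 2.07 in transition cambium and -0.40 in procambium (adjusted p = 0.00755, and 0.0501 without untreated procambium replicate 2). The count of 999 was 656 without untreated procambium replicate 2 and 592 without BAP-treated procambium replicate 3, and 541 with the probe sets higher in ARR5::GFP cells left out, a choice made after seeing the data on arrays that also enter the F test.

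ARR5::GFP cells were set against untreated ARR15::GFP procambium, although age, dissection and reporter all differ between these sorts. RCPG was at least 515-fold higher in ARR5::GFP cells (14.01 ± 0.29 against 3.35 ± 0.57, n = 2 each, adjusted p = 6.53e-07). CXE18 was at least 200-fold, sks16 at least 177-fold, hemb2 at least 162-fold, scpl28 at least 54.8-fold and GH9B6 at least 43.2-fold higher. The root hair expansins EXPA7 and EXPA18, both kept members of the epidermis list, were at least 13.1-fold and 12.1-fold higher, as both were adjusted over the list alone. XTH16 was at least 14.7-fold, SBTI1.1 at least 5.67-fold, ATMYC1, a bHLH factor, at least 4.6-fold and PDF2.5 at least 4.3-fold lower, Prx37 was at -5.72 (1 of 2 ARR5::GFP arrays at log2 5 or more), and the cortex marker PEP at least 2-fold lower.

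In all, 4244 of 13465 probe sets were called between these sorts, 1888 higher and 2356 lower in ARR5::GFP cells, and 2719 without untreated procambium replicate 2. PDF2.5 and PEP were lost without that array (adjusted p = 0.127 and 0.166) or without ARR5::GFP replicate 1 (0.0538 and 0.0877) or replicate 2 (0.073 and 0.11). With only these 2 groups in the limma fit, 397 probe sets were called higher and 259 lower in ARR5::GFP cells, so the excess of lower calls did not hold. Of 13 wounding, calcium and defence genes 10 were higher, with WRKY53 6.11-fold (camera adjusted p = 7.62e-06, and adjusted p = 0.19 with an estimated correlation). Of 8 kept auxin response genes 4 were higher and 1 lower, and 5 and 1 adjusted over the list alone, with GH3.17 21.2-fold higher. That list's camera call (adjusted p = 0.0291, and adjusted p = 0.104 with an estimated correlation) was lost without untreated procambium replicate 2 (0.0678) or ARR5::GFP replicate 1 (0.156).

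**Figure D3:**
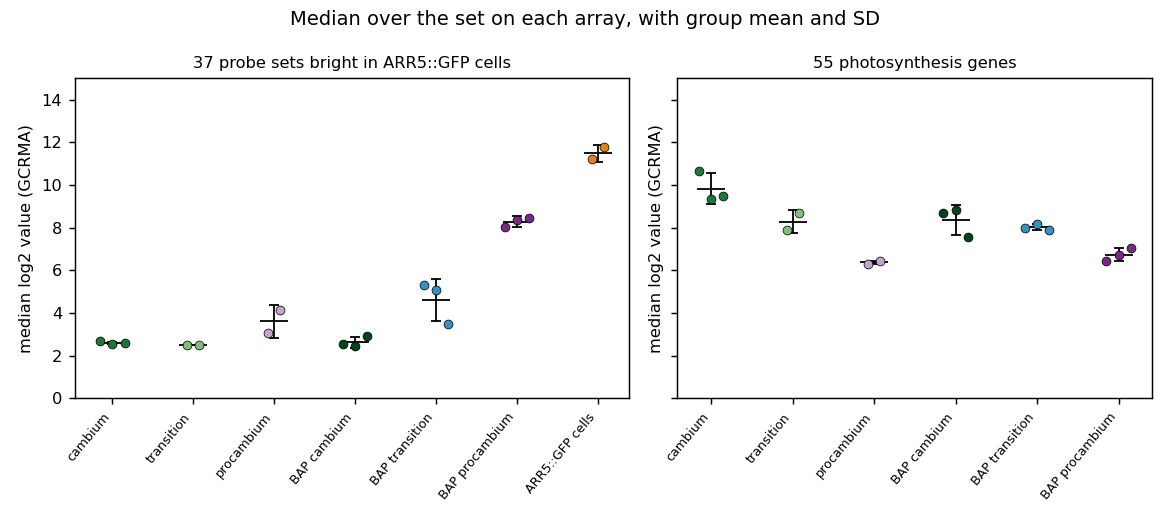
Median log2 value on each array of 37 probe sets that are bright in ARR5::GFP cells and dim in untreated transition cambium and procambium (left), and of 55 photosynthesis genes (right, ARR15::GFP arrays), with 1 point per array, grouped by sort, and lines for the group mean and SD. The 37 probe sets were chosen from these arrays, so their levels in those 3 sorts follow from the choice, and all 3 BAP-treated procambium arrays lie above every untreated array.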

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

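The tests of cells of another type in the BAP-treated procambium sort and of other root tissues in the cambium sort, and the counts without probe sets higher in ARR5::GFP cells, and the F tests of single genes with 1 array left out, were chosen after the results were seen.

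The response to BAP differed between root zones for 999 probe sets by limma's F test, with 1184 called for cambium minus procambium, 696 for transition cambium minus procambium and 49 for cambium minus transition cambium. No group holds the 4 to 10 arrays that a test for a single outlying array needs. The genes that follow were picked out because the effect of BAP differed between zones, and the values are the BAP effect in cambium minus that in procambium, on the log2 scale. Positive values were found for NANA (6.06), UGT84A4 (5.41), BGLU47 (4.57), GH9B5 (3.68), XTH21 (4.28), TBL37 (2.94) and GH9B13 (2.11). Negative values were found for RCPG, locus AT1G65570 (-7.83), GH9B6 (-7.44), hemb2 (-7.37), PPDK (-6.81), TPS-CIN (-5.43), GH9C1 (-4.76), STR18 (-3.40), JAL33 (-3.38), BGLU44 (-3.16), KICP-02 (-2.73) and WRKY53 (-2.73). ARPN (0.09) differed in transition cambium, where it was at least 6.71-fold lower with BAP. ROXY1 lay below log2 5 on every cambium and procambium array, so its fitted -3.73 cannot be read as a difference between them, and it was at least 2.49-fold lower with BAP in transition cambium. The F test of these 20 genes passed without any 1 of the 16 arrays.

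The F test was less stable for the other genes picked out in this way. SBTI1.1 (4.36) and AUR1 (3.25) missed the threshold without untreated procambium replicate 2 (adjusted p = 0.0502 and 0.0501). ZCF125 (2.53) missed it without untreated procambium replicate 1 (0.0544) or 2 (0.0918), and BGLU28 (3.41) without BAP-treated cambium replicate 2 (0.0517) or 3 (0.0611). LHW (-0.57) missed it without 6 of the 16 arrays, BAT1 (-2.88) without 7, sks15 (-3.75) without 10, SP1L2 (0.29) and TBL34 (2.65) without 13 each, and scpl28 (-4.81) without 14, with adjusted p-values up to 0.0839, 0.0805, 0.0759, 0.203, 0.101 and 0.0965. All 30 values are fitted differences and no bounds. For 20 of the genes, all but NANA, JAL33, TBL37, GH9B13, BAT1, PPDK, STR18, AUR1, WRKY53 and LHW, at least 1 of the 4 groups behind the value lay below log2 5 on every array, so the size depends on the background model. A fall could not be seen in procambium for TPS-CIN and ARPN, nor in cambium for XTH21 and GH9B5, which lay below that level there with and without BAP.

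Transcripts abundant in ARR5::GFP cells rose with BAP in the procambium sort. Of 37 probe sets at a mean of log2 10 or more in ARR5::GFP cells and below 5 on every untreated transition cambium and procambium array, 100% had a mean of at least 5 in BAP-treated procambium, against 51.4% in BAP-treated transition cambium and 8.1% in BAP-treated cambium. The BAP-treated transition cambium arrays differed, with 22, 19 and 9 of the 37 at log2 5 or more on replicates 1, 2 and 3. Their median BAP effect of 4.71 was still 4.58 after quantile normalization, so further scaling of the deposited values did not account for it. The ARR15::GFP arrays were already close in level (medians 7.17 to 7.43 over the probe sets kept), so this could hardly turn out otherwise. It cannot test the GCRMA step itself. The untreated side lay below log2 5 by choice, so the size depends on the background model. The 100% is what cells of another type, such as the root cap cells that the labels name for ARR5::GFP, would bring. The probe sets lay below their level in ARR5::GFP cells by 0.05 to 6.28 (median 3.22). That spread decides nothing here, since the labels place the ARR5 reporter in procambium and lateral root cap, and dim values depend on the background model. Cells of another type stay a candidate explanation, which the GFP gate would remove only if they lack GFP. A change of expression within procambium cells stays open and untested. So does a change of which cells were sorted, through a switch of the ARR15 reporter itself under BAP. RCPG is the 1 root cap marker of the fixed list that was measured. It is among the 37 probe sets, as are hemb2, sks16, GH9B6, scpl28 and CXE18, named above for BAP.

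Photosynthesis genes were higher in untreated cambium than in procambium, with a median log2 fold change of 3.06 over 55 listed genes. A single array is argued against, because the lowest median without 1 of the 5 arrays was 2.89. After quantile normalization and median centring the lower median was 2.98, but the deposited arrays were already close in level. That result therefore cannot test the scaling done in GCRMA. Cells of other root tissues in the cambium sort stay open: of the 2 kept cortex and root hair markers EXPA7 lay below log2 5 on every array of both zones, so their median of -0.63 decides nothing, and PEP (locus AT1G09750), at -1.48 (adjusted p = 0.358) with 1 of 3 cambium arrays at log2 5 or more, is too few. The zones are also parts of the root at different distances from the shoot, a biological difference that was not tested.

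Other splits of the arrays were compared with the real ones. For the averaged BAP effect, none of the other splits among 100 drawn within zones gave as many calls as the real 3984. The highest was 1158. A random division of the arrays within zones is therefore argued against as the source of that count. The other splits mix treated and untreated arrays, which widens their spread and lowers their counts. A batch of plants that went with the treatment would give the same result and is not excluded. The 10 splits of 6 arrays are too few for a share under 0.05. In these, the real value and the highest of the other splits were 4099 and 0 for cambium against procambium with BAP, 3863 and 1 for transition cambium against procambium with BAP, 167 and 2 for cambium against transition cambium with BAP, and 1962 and 8 for the BAP effect in cambium.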

How the results depend on the processing

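The settings that leave out probe sets higher in ARR5::GFP cells were chosen after seeing the data. The 129 gene and comparison pairs named by rule gave 2162 values over the alternatives, of which 2064 kept their direction and call, 98 lost the call and 0 reversed. The rule takes called, large changes whose arrays do not overlap in these same data. These shares therefore follow largely from the choice of genes and say little about how sturdy other calls are. Counts moved by over 1.5 times as follows, the cause not being tested except where fewer arrays or probe sets entered. With only the compared groups in the fit, they were 2542 for cambium and 1154 for transition cambium against procambium without BAP, 0 for cambium against transition cambium without BAP (limma, 856 at an unadjusted p under 0.05) and 62 with BAP, 772 and 709 for BAP in transition cambium and procambium, and 656 for ARR5::GFP cells. That limma fit also lost the calls of sks15 (adjusted p = 0.0574) and BCAT4 (0.0731) for BAP in transition cambium. It lost scpl28 and XTH16 (0.116 each) for BAP in procambium, and Prx37 (0.0867) for ARR5::GFP cells. The filter at log2 7 gave 66 for untreated cambium against transition cambium and 641 for the F test, no filter gave 82 for BAP-treated cambium against transition cambium, array weights gave 446 for that and 2419 for ARR5::GFP cells, and a minimum size of 1 gave 1820 for the averaged BAP effect. Without probe sets higher in ARR5::GFP cells, BAP in procambium gave 1161 and the F test 541, whose arrays include those of untreated transition cambium used for the choice. Of the 20 added lists, whose alternatives were also chosen after seeing the data, camera called 4 for cambium against procambium without BAP, fry 9, and camera with an estimated correlation 0 (2 at an unadjusted p under 0.05), with 3 to 6 when 1 array was left out. For the averaged BAP effect these counts were 4, 12 and 0 (2 at an unadjusted p under 0.05), 9 without a filter and 1 without untreated procambium replicate 2, and 7 without untreated transition cambium replicate 1, untreated procambium replicate 1, BAP-treated cambium replicate 2 or BAP-treated procambium replicate 3. By fry 1 fixed list was called for the averaged BAP effect, against 0 of 2 by camera. Leaving out each array in turn gave, without BAP, 3448 to 4587 for cambium against procambium, 1924 to 3025 for transition cambium against procambium and 16 to 219 for cambium against transition cambium, and with BAP 3067 to 3738, 2575 to 3454 and 76 to 177. The BAP effect ranged from 1019 to 1797 in cambium, 516 to 869 in transition cambium, 1185 to 1798 in procambium and 3131 to 4296 on average, the F test from 592 to 1038 and ARR5::GFP cells from 2719 to 4307. Fixed lists called ranged from 1 to 1 for cambium against procambium and 0 to 1 for the averaged BAP effect (1 without untreated procambium replicate 2). ARR15 lay below log2 5 on every untreated and ARR5::GFP array, so the signs of its differences there carry no information. Not called, it changed sign for untreated cambium against procambium, from -0.06 to 0 with a replicate block that numbers the second procambium array 3, 0.01 without cambium replicate 1 and 0.02 without replicate 2. For ARR5::GFP cells it changed sign from 0.16 to -0.21 without ARR5::GFP replicate 2 and kept it, at 0.54, without replicate 1. With the replicate number as a block the counts were 4211 for cambium against procambium without BAP, 3499 for the averaged BAP effect and 732 for the F test, and no count moved by over 1.5 times. With that block the calls of SBPASE (adjusted p = 0.0651), PSAN (0.0506), GUT2 (0.122) and ACLA-2 (0.113) between untreated cambium and transition cambium, of ARPN (0.076), hemb2 (0.0516) and SCPL34 (0.0518) between these zones with BAP, and of BCAT4 (0.0519) and LBD16 (0.0505) for BAP in transition cambium were lost, and PHV was called between untreated cambium and procambium (0.036). With the second procambium array numbered 3, PEP was lost for ARR5::GFP cells (0.0632). The deviations of 36 same-numbered pairs correlated at -0.52 to 0.28, and 2 of 16 arrays correlated best with their own number. Within a treatment, where zones could share plants, 15 such pairs correlated at -0.2 to 0.28. Their median was 0.06, against 0.01 for all pairs with different numbers. These values show little pairing, but with so few arrays per group they cannot exclude it, so the calls lost with the block stay uncertain. No fixed list kept 5 genes at log2 7, and the fit of compared groups alone was not run for the averaged effect and the F test, which use all 6 groups. No pseudocount was tried, since the values are log2. Signal over background limits these values, since probe sets near the floor carry no order.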

Other observations

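The overlaps between zones and the list results here were chosen after the main results were seen.

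With BAP in cambium, camera called further added lists as sets, each lost with an estimated correlation. Of 5 DNA replication genes 2 rose (adjusted p = 0.0217, and adjusted p = 0.261 with an estimated correlation), a set call lost without untreated cambium replicate 2 (0.0853). Of 17 IQD and TRM microtubule-associated genes 3 rose (adjusted p = 0.0169, and adjusted p = 0.261 with an estimated correlation), and of 7 tubulins 1 rose (adjusted p = 0.00837, and adjusted p = 0.261 with an estimated correlation). Of 12 beta-glucosidases 5 rose (adjusted p = 0.0169, and adjusted p = 0.261 with an estimated correlation), which was lost without untreated cambium replicate 2 (0.0768), and of 30 UDP-glycosyltransferases 4 rose (adjusted p = 0.00837, and adjusted p = 0.418 with an estimated correlation). In transition cambium 3 of 30 UDP-glycosyltransferases rose (adjusted p = 0.0171, and adjusted p = 0.697 with an estimated correlation), lost without untreated transition cambium replicate 1 (0.0768).

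Camera called added lists in further comparisons too, some of them lists named above, and each such call gave a higher adjusted p with an estimated correlation. In untreated cambium against transition cambium, DNA replication genes were lower as a set by camera (adjusted p = 0.0181, and adjusted p = 0.382 with an estimated correlation), with 0 of 5 called singly in limma and 3 at an unadjusted p under 0.05, a call lost without untreated cambium replicate 2 (0.222) or transition cambium replicate 1 (0.175). In the same comparison IQD and TRM genes were called lower as a set by camera alone (adjusted p = 0.035, and adjusted p = 0.382 with an estimated correlation). Of these genes 0 of 17 were called singly in limma and 3 had an unadjusted p under 0.05. The set call was lost without cambium replicate 1 (0.0951) or 3 (0.0972) or transition cambium replicate 1 or 2, and fry called neither list. Of 13 chaperone genes 2 were higher in BAP-treated cambium than procambium (adjusted p = 0.029, and adjusted p = 0.462 with an estimated correlation), lost without BAP-treated cambium replicate 3 (0.0687) or BAP-treated procambium replicate 1 (0.0527) or 3 (0.0849). In BAP-treated transition cambium against procambium, 13 of 39 plastid-encoded and 7 of 16 nuclear photosynthesis genes were higher (adjusted p = 0.00294 and 0.00993, and adjusted p = 0.685 for both with an estimated correlation). There, 3 of 10 genes of mitosis and cytokinesis were higher (adjusted p = 0.0291, and adjusted p = 0.633 with an estimated correlation), and 5 of 12 beta-glucosidases were higher and 1 lower (adjusted p = 0.0201, and adjusted p = 0.584 with an estimated correlation). Of 7 tubulins 1 rose with BAP in transition cambium (adjusted p = 0.0192, and adjusted p = 0.415 with an estimated correlation), lost without untreated transition cambium replicate 2 (0.2) or BAP-treated transition cambium replicate 3 (0.051). In ARR5::GFP cells 6 of 39 plastid-encoded photosynthesis genes were higher than in untreated procambium (adjusted p = 0.00704, and adjusted p = 0.701 with an estimated correlation), lost without ARR5::GFP replicate 2 (0.336).

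The BAP effects of different zones share no arrays. Across probe sets, which are not independent replicates, they correlated at r = 0.594 for cambium and transition cambium, 0.43 for transition cambium and procambium and 0.261 for cambium and procambium. Cambium and transition cambium shared 352 probe sets that rose and 313 that fell, where independent lists would share 47.9 and 44.3. Cambium and procambium shared 175 and 179, where independent lists would share 77.5 and 60.8, and transition cambium and procambium shared 211 and 157, against 47.3 and 39.9. Over the probe sets kept, ARR5::GFP arrays correlated at a mean of 0.822 with BAP-treated procambium arrays (0.754 to 0.872 over pairs). With untreated procambium arrays the mean was 0.766 (0.733 to 0.815), so the ranges overlap.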
